A study of Homo sapiens with 20 samples.

How the data were processed

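The series holds 20 RNA-seq libraries of human naive CD4 T cells, 14 from a time course of activation and 6 from electroporated cells. Per the labels, libraries were made from polyadenylated RNA with a stranded dUTP kit. The authors deposited 1 table per library with raw read counts and with RPKM values (reads scaled to transcript length and to the mapped reads of the library). Each deposited table has 29800 entries, 1 for each set of RefSeq transcripts of a gene that share a transcription start, with positions in genome build hg19. Per the submitters' processing notes, STAR 2.4.0c, Bowtie 1.0.0 and MACS2 2.1.0.20140616 were used in the series, with no role or order given. How reads in shared exons were allotted between the entries of a gene, and whether strand was used in counting, is not given in the sources used here.

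Counts were summed per gene name, which gave 23328 genes, 3591 of them from more than 1 entry. A gene name can join several symbols (259 names), and 1512 entries lie on alternative or unplaced sequences. XIST, TSIX and all genes of chromosome Y (172 entries) were left out of all steps. RPKM values were used only to recover transcript length (13373 genes with at least 20 counts) and the number of mapped reads, of which 67.1% to 88.1% fell in genes. Total counts per library ran from 2020137 to 20338310. Replicates correlated with r from 0.925 to 0.974 on log CPM with a prior count of 2, and the SD of their log2 difference ran from 0.68 to 1.04.

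Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by its robust quasi-likelihood F test, two-sided, with TMM scaling, filterByExpr at a minimum count of 10 and total of 15, and Benjamini-Hochberg adjustment at 0.05. One fit covered the 14 time course libraries (12892 genes, common biological coefficient of variation 0.361), another the 6 electroporated libraries (12583 genes, 0.395) and another all 20 (13416 genes) for the interaction with electroporation. TMM factors ran from 0.758 to 1.245 over the 3 fits. There were 12 comparisons, 8 main and 4 secondary, and 3 interactions. In the text "raised" and "lowered" mean an adjusted p under 0.05. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison, with an estimated correlation, and with fry. DESeq2 1.42.0 was an alternative. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

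The groups, tests, alternatives, 26 gene lists and rule for named genes were fixed before the data were examined. The lists hold AP-1 family, immediate early and feedback, NF-kB target, cytokine, chemokine, activation surface, naive and quiescence, anergy-associated, helper lineage factor, DNA replication, mitosis, glycolysis, cholesterol, amino acid and one-carbon, ribosome biogenesis, BCL2 family, interferon-stimulated, heat shock, p53 and housekeeping genes, and markers of myeloid, B, NK and cytotoxic, CD8 T, memory and regulatory T, and platelet or erythroid cells. All 409 list entries matched a gene in the tables. Per main comparison, the rule named the 5 largest rises and 5 largest falls (3 for secondary comparisons) among genes that passed, with log2 CPM that did not overlap between groups and a mean of at least 10 CPM in the higher group. It also named up to 3 members per list with the smallest p among those that passed, and 10 fixed genes (FOS, FOSB, FOSL1, FOSL2, JUN, JUNB, JUND, BATF, IL2 and IFNG). HLA genes and small or uncharacterised RNA genes were left out of naming. Under the replicate block the same rule was used, with the genes of smallest p added after the data were seen. The GBP genes, as a family, were also chosen after their values were seen.

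Same-numbered libraries share a preparation tag in the labels, so the numbers were taken to pair the samples. Deviations from the group means of same-numbered libraries had correlations over 0.1 in 16 of 21 pairs of groups in the time course (median 0.284, from -0.086 to 0.618) and in 2 of 3 in the electroporation experiment (median 0.303, from 0.088 to 0.373). The group with both antibodies at 60 h had correlations from -0.086 to 0.115 with the other time course groups, so the pairing has little support for it. The fit with the replicate number as a block, an alternative, had coefficients of variation of 0.287 and 0.315.

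Where a group had 0 counts, a fold is given as a lower bound with the group set at 3 counts over its libraries. With 1 to 3 counts, the ratio is given with its exact 95% interval. For comparisons that share the naive libraries, 20 simulated draws of unchanged groups gave the overlap and correlation of fold changes that arise with no effect.

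The count steps were tested on simulated counts for the real genes, with 200 genes changed. At a 4-fold change edgeR recovered 37.5% of them for both antibodies against naive cells at 5 h, 43% for co-stimulation at 24 h (both over 12892 genes), 40.5% for A-FOS against GFP and 50% for GFP against unactivated cells (over 12583 genes). DESeq2 recovered 61.5%, 63%, 54% and 67.5%, with up to 39 wrong calls against up to 9 for edgeR. At 2-fold edgeR recovered 0.5% for A-FOS against GFP and 0% in the other 3, and DESeq2 6% to 8%. At 2-fold DESeq2 made 12 right and 21 wrong calls for both antibodies at 5 h, and 12 and 11 for co-stimulation at 24 h. For A-FOS against GFP it made 13 and 14, and for GFP against unactivated cells 16 and 15. In this simulation DESeq2 thus did not hold its share of wrong calls to the threshold, so genes that DESeq2 alone called are uncertain. An interaction of 4-fold in the co-stimulation effect between 24 h and 60 h was recovered for 4.5% of genes. The share recovered depends on the number of changed genes, so it sets no limit for the comparisons with naive cells, where many more genes passed and smaller changes did too.

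The alternatives were DESeq2 size factors in edgeR, total counts as the only scaling, no filter on low counts, DESeq2, the replicate block, a fit of only the 4 libraries compared, a fit of all 20 libraries, and each library of the groups left out in turn, with the remaining library of that group assumed to vary like the others. Added after the data were seen were the block in a fit of the 4 libraries, the block without the group at 60 h with both antibodies, genes overlapping another on the same strand left out, transcripts of at least 1000 bases for A-FOS, a separate naive library for each of 2 comparisons, and a set of 200 genes for co-stimulation.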

Results

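Transcript levels were measured by poly(A) RNA-seq in human naive CD4 T cells purified from blood mononuclear cells, in 20 libraries that form 10 groups of 2. The time course held 14 libraries in 7 groups. These were cells that had not been activated (naive cells), cells activated for 5, 24 or 60 h with beads carrying antibodies against CD3 and CD28, and cells activated for the same times with antibody against CD3 and no CD28 antibody. CD3 is the signalling part of the T cell receptor complex, and CD28 is the main co-stimulatory receptor of naive T cells. The electroporation experiment held 6 libraries in 3 groups. These were cells pulsed without protein and not activated, cells pulsed with green fluorescent protein (GFP) and activated for 5 h through CD3 and CD28, and cells pulsed with A-FOS and activated in the same way. Electroporation opens the cell membrane briefly with an electric field, so that protein can enter. A-FOS is a dominant-negative protein that pairs with JUN proteins and keeps AP-1, the FOS and JUN transcription factor dimer, off DNA. GFP has no role in transcription and served as the control protein.

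Reads counted in genes came to 10543230 and 2020137 in naive replicates 1 and 2. With both antibodies they came to 9928594 and 7704460 at 5 h, 10735236 and 9336583 at 24 h, and 11164474 and 8193543 at 60 h. With CD3 antibody alone they came to 19842137 and 7814510 at 5 h, 10339329 and 7226257 at 24 h, and 20338310 and 6638972 at 60 h. The electroporated libraries held 5936161 and 19017629 reads without activation, 11187042 and 18981019 with GFP, and 8664760 and 20140677 with A-FOS. Changes below are log2 fold changes ± standard error, levels are CPM (counts scaled to library size) as mean ± SD, and n = 2 libraries per group throughout. The labels do not say that the replicates came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical. Intervals and lower bounds on folds cover counting error only. The labels give no time in culture for cells that were not activated, and the same naive group served 5, 24 and 60 h. In comparisons with unactivated cells, activation and time in culture therefore cannot be told apart. Gene positions are in genome build hg19. Of the genes named below, UHRF1, COL5A2, CXCR3, ACY1, C7orf50 and RPL17 overlap another gene on the same strand. CD27, ECE1, FOXM1, KLF3, PTPN22, RNF157-AS1, SHMT2, TAP1, TMEM140, TMEM204 and TOB1 overlap a gene on the other strand, and whether the counting used strand is not given, so all of these are uncertain.

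The comparison of cells activated for 5 h through CD3 and CD28 with naive cells asks which transcripts change early in T cell activation. The raised genes included genes of cytokines, of a transcription factor and of an amino acid transporter, and the lowered ones included 12 of 22 naive and quiescence genes. IL2, the growth factor cytokine of T cells (chromosome 4, 123372626 to 123377650), stood at 2080 ± 2180 CPM, with 546 and 3620 CPM in the replicates and 2 counts in the naive libraries together. That is a ratio of 12500 with a counting interval of 3470 to 103000. IRF4, a transcription factor induced by T cell receptor signals, stood at 5560 CPM against 20.7 CPM in naive cells (8.04 ± 0.55). SLC7A5, a transporter of large neutral amino acids, stood at 7260 against 10.6 CPM (9.31 ± 1.0), and TNF, an inflammatory cytokine, at 2100 ± 552 against 5.27 CPM (8.49 ± 0.91). TXNIP, which restrains glucose uptake, was 42.2-fold lower (-5.40 ± 0.41). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, the adjusted p was 0.00077 for IL2, 7.2e-06 for IRF4, 4.6e-05 for SLC7A5 and TNF, and 1.1e-05 for TXNIP.

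Among large rises at 5 h, XIRP1, which codes for an actin-binding repeat protein (chromosome 3, 39224706 to 39234085), stood at 625 ± 624 CPM and at 0 counts in naive cells, at least 2510-fold higher. HCAR1, the lactate receptor gene, was at least 320-fold higher, HIC1, a transcriptional repressor gene, at least 259-fold and CHAC1, a stress-induced glutathione-degrading enzyme gene, at least 262-fold. Falls to 0 counts were in RNF157-AS1 (at least 244-fold lower), SIAH3 (at least 154-fold), FAM63A (at least 148-fold), GDPD3 (at least 96.4-fold) and DPYSL2 (at least 76.6-fold).

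Of the 10 AP-1 family genes tested at 5 h, 8 rose and none fell. BATF rose by 5.10 ± 0.38 (185 against 5.3 CPM), FOSL2 by 5.43 ± 0.80, FOS by 6.61 ± 1.39 and JUNB by 3.09 ± 0.76. FOSL1 (chromosome 11, 65659692 to 65667997) stood at 260 ± 7.92 CPM against 1 count in naive cells, a ratio of 3370 with a counting interval of 604 to 133000. FOSB rose by 4.97 ± 1.45. The members that did not pass were JUN at 0.52 ± 1.03 and JUND at 0.97 ± 0.55. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 1e-05 for BATF, 3e-05 for FOSL1, 0.00024 for FOSL2, 0.0021 for FOS, 0.0054 for JUNB and 0.013 for FOSB, and 0.7 and 0.16 for JUN and JUND. In the same test the adjusted p of FOSB was 0.078 without naive replicate 2 (4.29) and 0.075 without replicate 1 of the 5 h group (3.56), and that of JUNB was 0.052 without naive replicate 2 (2.81).

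Immediate early and feedback genes, which respond to receptor signals within hours or damp them, had 16 of 18 tested members raised and none lowered. DUSP4 and DUSP2, phosphatases of MAP kinases, rose by 7.47 ± 0.70 and 6.62 ± 0.62. NF-kB target genes had 12 of 15 raised, with REL at 5.67 ± 0.44 and NFKB1 at 4.09 ± 0.37, both subunits of NF-kB. Cytokine genes had 14 of 16 raised and 15 adjusted over the list alone, with TNFSF14 (LIGHT) at 8.98 ± 0.79. IFNG stood at a ratio of 2140 with a counting interval of 731 to 10400. Chemokine genes had 7 of 10 raised, with CCL4 at 7.55 ± 1.39 and IL8 at 3.39 ± 0.72. Surface molecules of activated T cells had 18 of 20 raised. IL2RA, the inducible IL-2 receptor chain, was 173-fold higher (7.43 ± 0.67), and TNFRSF9 (4-1BB) stood at 776 against 0.286 CPM. For these named genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave values from 1.3e-05 (REL) to 0.0063 (IFNG). The adjusted p of IFNG in that test was 0.064 without naive replicate 1.

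All 21 ribosome biogenesis genes rose at 5 h, among them NOLC1 at 4.07 ± 0.43, RRP9 at 4.56 and RRS1 at 3.74. Glycolysis genes had 12 of 17 raised and 1 lowered, or 14 raised and 2 lowered adjusted over the list alone, with PKM at 4.25 ± 0.37. Amino acid transport and serine one-carbon genes had 10 of 14 raised and 1 lowered, with the glutamine transporter SLC1A5 at 7.85. Cholesterol genes had 9 of 17 raised and 1 lowered, with HMGCS1 at 4.26 ± 0.86. Heat shock genes had 10 of 16 raised and 1 lowered, with HSP90AB1 at 3.94 ± 0.38. Of the helper lineage transcription factors 8 of 16 rose and 1 fell, with TBX21, the Th1 regulator, at 8.71 ± 0.65 and IRF8 at 9.98 ± 1.06. BCL2 family genes had 6 of 14 raised and 2 lowered, with the survival gene BCL2A1 at 6.71 ± 0.79 and the death-promoting gene PMAIP1 at 6.58. The p53 list had 7 of 16 raised and 5 lowered, with GADD45A at 6.04 ± 0.48 and CDKN1A, the cell cycle inhibitor p21, at 5.72.

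Some lists held members that moved both ways at 5 h. Of 22 naive and quiescence genes 12 fell and 4 rose, with TOB1 at -2.48 and BACH2, a repressor that keeps T cells quiescent, raised by 2.56 ± 0.35. Anergy-associated genes had 6 of 13 raised and 4 lowered. PTPN22, a phosphatase that limits receptor signalling, rose by 4.96 and CBLB, a ubiquitin ligase that restrains activation without co-stimulation, by 2.93 ± 0.35, while the diacylglycerol kinase gene DGKA changed by -4.82 ± 0.54. Interferon-stimulated genes had 3 of 19 raised and 7 lowered, or 11 lowered adjusted over the list alone. MX2, an antiviral GTPase gene, was at -4.04 ± 0.54. DNA replication genes had 2 of 24 raised and 5 lowered, or 1 and 5 adjusted over the list alone, with CCNE1 at -3.27 ± 0.48. None of 22 mitosis genes rose and 6 fell, or 4 adjusted over the list alone, with CENPF at -2.95 ± 0.35. Of 12 housekeeping genes 6 rose and 1 fell, with PPIA at 1.41 ± 0.30.

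Markers of other cells were few at 5 h. Of 4 tested B cell genes 2 fell, with CD79B at a ratio of 119 below naive cells (counting interval 20.9 to 4730). Of 4 myeloid genes AIF1 fell, and of 9 NK and cytotoxic genes GZMB (5.28 ± 1.13) and PRF1 (2.13), which activated T cells also express, rose. Memory and regulatory T cell markers had 3 of 12 raised and 2 lowered, no CD8 T cell marker of 2 tested passed, and no platelet or erythroid gene reached the tested set in any comparison. The calls of AIF1, BLK, PRF1 and CXCR3 were lost in at least 1 fit without a library.

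In total 6529 of 12892 genes tested differed between cells activated for 5 h and naive cells, 2947 raised and 3582 lowered. The count was 7444 with the replicate number as a block. With total counts as the only scaling, which moved the median log2 fold change by -0.48, 2033 genes were raised and 4777 lowered. Camera with a preset correlation and Benjamini-Hochberg adjustment over the 25 lists with a tested member placed 12 lists above the other genes. Adjusted p ran from 7e-17 for ribosome biogenesis to 0.047 for cholesterol genes, and with an estimated correlation the adjusted p of these 12 ran from 0.027 to 0.62. Activation surface molecules alone passed with an estimated correlation (camera adjusted p = 0.027, or 0.051 with the replicate block). The BCL2 family and the naive genes passed camera with the replicate block only, at adjusted p = 0.029 and 0.032 against 0.064 and 0.08, and had adjusted p = 0.19 and 0.51 with an estimated correlation. Naive replicate 2 was the shallowest library of the series, and it enters every comparison with naive cells.

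The comparison at 24 h asks what had changed at the middle time. Genes for DNA replication had risen and genes of naive cells had fallen further in number. MCM2, a helicase subunit that licenses replication origins, rose by 5.21 ± 0.50 from 20.2 to 764 CPM, and all 24 DNA replication genes rose. UHRF1, which couples DNA methylation to replication, was at least 927-fold higher (214 ± 22.9 CPM), MCM10 at least 637-fold, the checkpoint adaptor gene CLSPN at least 476-fold and the exonuclease gene EXO1 at least 341-fold. IL2 stood at 3150 ± 3350 CPM, a ratio to naive cells of 19200 with a counting interval of 5310 to 158000. KLF2, a transcription factor that maintains quiescence, stood at 0.0445 against 209 CPM, a ratio of 4820 below naive cells with a counting interval of 864 to 190000. RASGRP2, a RAP1 activator of resting lymphocytes, fell by 10.69 ± 1.82 to 0.557 CPM. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, the adjusted p was 9.2e-05 for MCM2 and 0.00092 for RASGRP2.

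Mitosis genes had 20 of 22 raised at 24 h, with BUB1, a spindle checkpoint kinase, at 4.34 ± 0.55 and TOP2A at 5.28 ± 0.70. All 21 ribosome biogenesis genes were raised, with NOLC1 at 3.05. Of the 18 immediate early genes 16 rose, with DUSP4 at 7.74 ± 0.70. AP-1 family genes had 3 of 10 raised, with BATF at 4.01 ± 0.36 and FOSL1 at a ratio of 905 (162 to 35800). FOS stood at 1.15 ± 1.36, FOSL2 at 0.97, JUNB at 1.38 and JUN at -2.35, and none of these passed. Cytokine genes had 12 of 16 raised, 14 adjusted over the list alone, with TNF at 7.73 ± 0.88 and LIF at 10.64 ± 1.43. NF-kB targets had 11 of 15 raised and 1 lowered, with NFKB1 at 2.51 ± 0.35, and chemokines had 5 of 10 raised and 1 lowered, CCL5 at -3.58 ± 0.56. Surface molecules had 12 of 20 raised and 1 lowered, with IL2RA at 7.45 ± 0.67 and the inhibitory receptor gene PDCD1 at 7.23 ± 0.66. Helper lineage factors had 3 of 16 raised and 5 lowered, with IRF4 at 5.36 ± 0.48. Amino acid genes had 11 of 14 raised, with MTHFD1, a folate-cycle enzyme, at 3.58 ± 0.37, and glycolysis genes 12 of 17.

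Of the 22 naive and quiescence genes 18 fell at 24 h and none rose, with KLF3 at -4.10 ± 0.54 and SATB1 at -3.76. Interferon-stimulated genes had 10 of 19 lowered and 1 raised, with the nuclease gene ISG20 at -4.63 ± 0.57 and MX1 at -4.05 ± 0.57. Anergy-associated genes had 5 of 13 raised and 7 lowered, with EGR2 at 6.47 and TLE4 at -3.26. BCL2 family genes had 5 of 14 raised and 3 lowered, with BCL2L1 (BCL-XL) at 4.47. The p53 list had 1 of 16 raised and 4 lowered, SESN1 at -3.66 ± 0.72. Heat shock genes had 8 of 16 raised and 2 lowered, cholesterol genes 2 of 17 raised (7 raised and 1 lowered with the replicate block), and housekeeping genes 4 of 12 raised, ACTB at 1.85 ± 0.29. Among markers of other cells, NK and cytotoxic genes had 1 of 9 raised and 4 lowered, memory and regulatory T cell markers 3 of 12 raised and 3 lowered, CD8 markers 1 of 2 lowered, myeloid markers 1 of 4 lowered and B cell markers 1 of 4 lowered.

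At 24 h 5961 genes differed from naive cells by edgeR's quasi-likelihood test, 3016 raised and 2945 lowered. The count was 3131 without replicate 2 of the 24 h group. IFNG, at a ratio of 141 to naive cells (48.1 to 686), had an adjusted p of 0.045 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without naive replicate 1 this was 0.21, without naive replicate 2 0.15 and without replicate 2 of the 24 h group 0.38, in the same edgeR test with Benjamini-Hochberg adjustment. Camera called 13 lists, from an adjusted p of 1.9e-19 for DNA replication to 0.014 for the AP-1 family, and with an estimated correlation the adjusted p of these 13 ran from 0.13 to 0.31.

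The comparison at 60 h asks what had changed after the longest activation. Mitosis and replication genes were raised throughout their lists. MKI67, a marker of cycling cells, stood at 904 ± 85.5 against 1.57 CPM (9.17 ± 0.70), and TOP2A at 758 against 0.62 CPM (9.69 ± 0.78). RRM2, a subunit of ribonucleotide reductase (chromosome 2, 10262695 to 10271546), stood at 308 ± 7.92 CPM and at 0 counts in naive cells, at least 1330-fold higher. IL7R, the receptor for the survival cytokine IL-7, stood at 71.4 against 2350 CPM (-5.04 ± 0.81). OAS1, an antiviral enzyme induced by interferon, stood at 193 against 2.36 CPM (6.36 ± 0.67). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 4e-05 for MKI67, 0.0011 for IL7R and 0.00011 for OAS1.

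All 22 mitosis genes and all 24 DNA replication genes rose at 60 h, among them CDC6, which loads the replicative helicase, at 7.40 ± 0.75, and CENPF at 4.22 ± 0.33. Other large rises were DLGAP5 (at least 890-fold), G0S2 (at least 632-fold), TK1 (at least 560-fold) and CBS (at least 544-fold). Naive and quiescence genes had 21 of 22 lowered, with IL6R at -3.40 ± 0.43 and KLF2 at a ratio of 1680 below naive cells (574 to 8140). WNT7A was at least 208-fold lower and GZMK at least 84.5-fold. Interferon-stimulated genes had 15 of 19 raised and none lowered, 16 adjusted over the list alone, with IFIT3 at 5.92 ± 0.86. AP-1 family genes had 5 of 10 raised. BATF was raised by 4.35 ± 0.37 and ATF3 by 6.35, while FOS (2.01), JUN (-1.09) and JUNB (1.70) did not pass. FOSL2 rose by 2.53 ± 0.71, with an adjusted p of 0.015 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the same test this was 0.084 without naive replicate 2 (1.91) and 0.053 without replicate 2 of the 60 h group (2.47).

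IL2 stood at 222 ± 192 CPM at 60 h, and its adjusted p of 0.005 was 0.059 without naive replicate 1, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cytokine genes had 8 of 16 raised at 60 h, with LTA at 4.25, and 1 of 10 chemokine genes was raised and 1 lowered, or none adjusted over the list alone. Surface molecules had 15 of 20 raised and 1 lowered, with IL2RA at 7.59 ± 0.68. Immediate early genes had 12 of 18 raised, 14 adjusted over the list alone, NF-kB targets 8 of 15 and helper lineage factors 5 of 16, with 4 lowered. Amino acid genes had 13 of 14 raised, with SHMT2, the mitochondrial serine enzyme, at 4.45 ± 0.49. Glycolysis genes had 13 of 17 raised, with GAPDH at 3.61 ± 0.44, and cholesterol genes 7 of 17 (12 with the replicate block). Ribosome biogenesis genes had 14 of 21 raised, with NPM1 at 1.76 ± 0.36. Heat shock genes had 10 of 16 raised and 1 lowered, the p53 list 5 of 16 raised and 1 lowered with CDKN1A at 4.71, and housekeeping genes 4 of 12 raised. BCL2 family genes had 6 of 14 raised and 1 lowered, the death-promoting gene BCL2L11 at -3.01 ± 0.63. Anergy-associated genes had 4 of 13 raised and 6 lowered, with the inhibitory receptor gene LAG3 at 5.13 ± 0.91. Among other-cell markers, NK and cytotoxic genes had 1 of 9 raised and 3 lowered (GZMB at 6.84 ± 1.19), myeloid 2 of 4 raised and 1 lowered, memory and regulatory 2 of 12 raised and 2 lowered, CD8 1 of 2 lowered and B cell none of 4.

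At 60 h 5149 genes differed from naive cells by edgeR's quasi-likelihood test, 2741 raised and 2408 lowered. The count was 3014 without naive replicate 1, 2942 without replicate 1 of the 60 h group and 3172 without its replicate 2. Camera called 14 lists, from an adjusted p of 7.2e-40 for mitosis to 0.014 for cholesterol genes, and with an estimated correlation the adjusted p of these 14 ran from 0.029 to 0.56. Mitosis genes and surface molecules passed with an estimated correlation, both at adjusted p = 0.029 with camera, and at 0.051 and 0.054 with the replicate block. Replicate differences of this 60 h group and naive cells correlated at -0.015. The pairing that the block assumes thus has little support in this comparison.

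**Figure D1:**
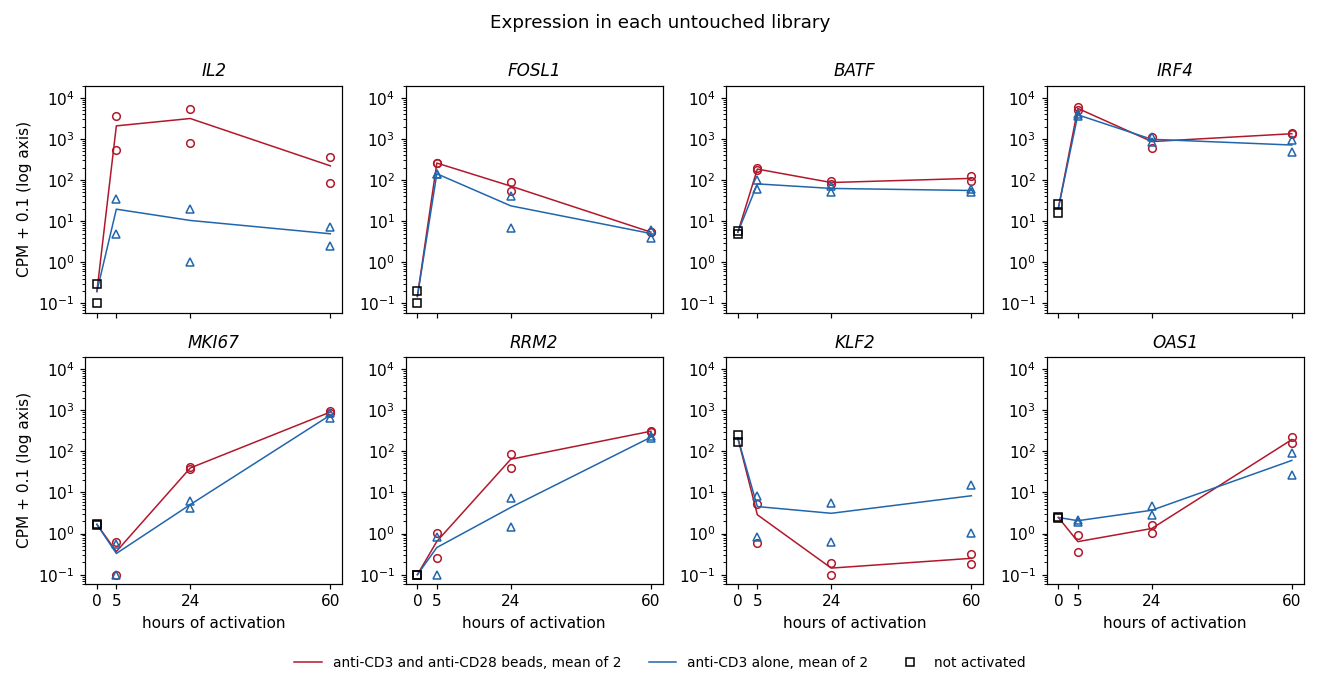
Expression of 8 genes in the 14 untouched libraries, in CPM plus 0.1 on a log axis, against hours of activation. Circles are libraries with antibodies to CD3 and CD28, triangles libraries with CD3 antibody alone, squares naive libraries, and lines join the means of 2 libraries. IL2 stands above 80 CPM in every library with both antibodies and below 35 CPM in every library with CD3 antibody alone, while IRF4 and BATF rise in both arms.

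**Figure D2:**
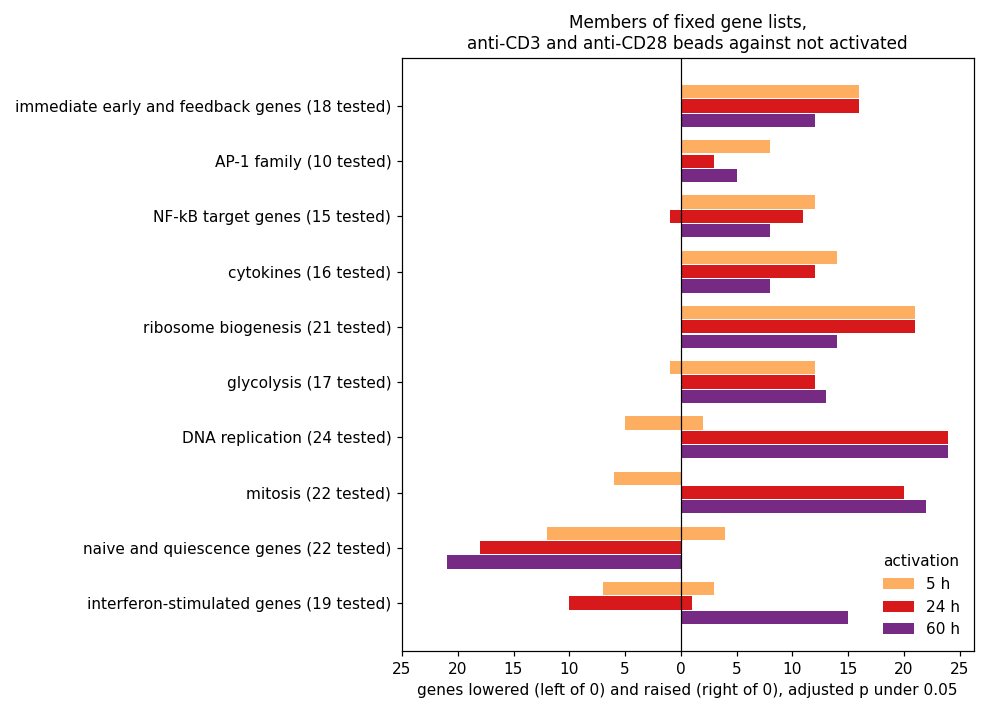
Number of genes of 10 fixed lists raised (right of 0) and lowered (left of 0) at an adjusted p under 0.05, in cells activated through CD3 and CD28 against naive cells at 5, 24 and 60 h. DNA replication and mitosis genes are raised from 24 h, and interferon-stimulated genes go from 7 lowered at 5 h to 15 raised at 60 h.

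Cells activated with CD3 antibody alone were set against the same naive cells to show what changed without CD28 antibody. The receptor signal and time in culture cannot be told apart here. At 5 h 9 of 10 AP-1 family genes rose, with BATF at 3.91 ± 0.36 and FOSL1 at a ratio of 1850 to naive cells (332 to 73200), and 16 of 18 immediate early genes and all 21 ribosome biogenesis genes rose. IL2 stood at 19.5 ± 20.9 CPM, a ratio of 88.9 with a counting interval of 24.4 to 738 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.028). Other changes were in HIC1 (at least 319-fold higher), CHAC1 (at least 295-fold), XIRP1 (at least 188-fold) and DSC1 (at least 106-fold lower). At 24 h 19 of 24 DNA replication genes and 12 of 22 mitosis genes were raised, with UHRF1 at least 249-fold higher, and 13 of 22 naive genes were lowered. At 60 h 23 of 24 and 22 of 22 were raised, with RRM2 at least 923-fold and TK1 at least 591-fold higher, 11 of 22 naive genes were lowered and 10 of 19 interferon-stimulated genes raised. Among the falls, SDK2, an adhesion molecule gene, was at -7.19 ± 1.14 at 24 h and -6.80 at 60 h. In total 5718 genes changed at 5 h (2687 raised, 3031 lowered), 2420 at 24 h (1518 and 902) and 2261 at 60 h (1559 and 702). These counts were 6803, 3843 and 3704 with the replicate block. With total counts as the only scaling 1857 genes rose and 4115 fell at 5 h, where that scaling moved the median by -0.43. The count was 3585 at 5 h without replicate 2 of that group. At 24 h it was 1549 and 695 without naive replicates 1 and 2 and 655 without replicate 2 of the CD3 group, and at 60 h 1297, 864 and 739. Surface molecules passed camera with an estimated correlation at all 3 times, at adjusted p = 0.026, 0.043 and 0.018, as did mitosis genes at 60 h at 0.018.

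The calls with and without CD28 antibody overlapped. The 2 arms were sampled at the same times, so shared calls can include effects of time in culture. At 5 h 2538 genes were raised and 2832 lowered in both, against 614 and 842 for independent lists. At 24 h the numbers were 1385 and 845 against 355 and 206, and at 60 h 1410 and 620 against 331 and 131. Across genes, which are not independent replicates, the fold changes had r = 0.936, 0.863 and 0.89 and covariances of 5.62, 3.69 and 4.30. In 20 simulated draws of unchanged groups against the same naive libraries no call was shared, the median r was 0.221 and the median covariance 0.088. The median number of calls in each simulated list was 0, so a shared call could hardly arise. The draws therefore do not show how far shared naive libraries raise the overlap of long lists. In a check added after the data were seen, each comparison had its own naive library. At 5 h, 1556 genes were then raised in both and 1775 lowered with naive replicate 1 set against both antibodies (362 and 500 for independent lists), and 1570 and 1835 the other way round (341 and 489). The correlation was 0.754 and 0.781 at 5 h, 0.619 and 0.691 at 24 h and 0.675 and 0.733 at 60 h.

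The direct comparison of both antibodies with CD3 antibody alone asks what CD28 co-stimulation adds. At 5 h no single gene passed. IL2 stood at 2080 ± 2180 against 19.5 ± 20.9 CPM (6.76 ± 1.66). In replicate 1 IL2 stood at 545.5 CPM with both antibodies and 4.753 CPM with CD3 antibody alone, and in replicate 2 at 3623 and 34.29 CPM. Both arms were higher in replicate 2, so these SDs do not measure the spread of the difference between same-numbered libraries. BATF stood at 185 against 80.7 CPM (1.20 ± 0.31) and FOSL1 at 0.86 ± 0.58. The other fixed AP-1 genes stood at 0.08 ± 0.99 for FOS, 0.28 for FOSB, 0.33 for FOSL2, -0.18 for JUN, 0.57 for JUNB and -0.58 for JUND, and IFNG at 1.22 ± 1.63. The adjusted p was 0.66 for IL2 and BATF by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.0088 and 0.049 by DESeq2. IL2 had an adjusted p of 0.093 with the replicate block, and 8.5e-07 with the block in a fit of the 4 libraries compared, by the same edgeR test with Benjamini-Hochberg adjustment. The genes with the smallest p under the block, chosen after their values were seen, were higher with both antibodies for DUSP6, a phosphatase of ERK (157 and 168 against 7.49 and 5.96 CPM), ECE1 and the cytokine gene IL23A, and lower for TXNIP (21 and 17.3 against 104 and 106 CPM), the kinase gene LCK and MYB. All 6 had an adjusted p of 0.064 in edgeR's quasi-likelihood test with the replicate block and Benjamini-Hochberg adjustment.

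As groups, cytokine genes were placed higher by camera at 5 h, with 1 of 16 passing adjusted over the list alone. NF-kB targets had a median of 0.57, with none of 15, and activation surface molecules 0.63. The camera adjusted p of the 3 lists was 2.6e-15, 1.8e-07 and 0.00081, and with an estimated correlation adjusted p = 0.14 for each. AP-1 family genes had a median of 0.34, with 1 of 10 raised adjusted over the list alone, and interferon-stimulated genes -0.59 (camera adjusted p = 0.0061 and 0.0016, or adjusted p = 0.6 and 0.66 with an estimated correlation). Chemokine and naive genes passed camera with the replicate block only, at adjusted p = 0.01 and 0.037 against 0.05 and 0.14, and had adjusted p = 0.33 and 0.74 with an estimated correlation. EdgeR called 0 of 12892 genes, with 635 at an unadjusted p under 0.05, about the share of 0.05 that arises with no effect. DESeq2, which made more wrong calls than edgeR in simulation, called 28 and edgeR with the block 0. The block gave 22 genes in a fit without the group with both antibodies at 60 h, and 1052 in a fit of the 4 libraries compared, 506 higher and 546 lower, both chosen after the data were seen. The replicate differences of the 2 groups at 5 h correlated at 0.593, so the absence of calls depends on the fit. The count was 1 without replicate 1 of the CD3 group at 5 h.

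After 24 h 64 genes differed with CD28 co-stimulation, 12 higher and 52 lower. Higher genes included IL1R1, the receptor for interleukin-1 (chromosome 2, 102770402 to 102796334), at 27.2 ± 1.32 against 0.796 ± 0.486 CPM (5.13 ± 0.74), and the proliferation genes FOXM1 (3.04 ± 0.52), MKI67 (2.99 ± 0.52) and AURKB, at a ratio of 27.3 with a counting interval of 7.24 to 231. FAM40B stood at 4.54 ± 0.69 and the collagen gene COL5A2 at 4.61 ± 0.82. Lower genes included CBLB (-2.01 ± 0.33, 29.5 against 119 CPM), BCL2L11 (-3.58 ± 0.64), BCL2 (-1.78 ± 0.35), the interferon-stimulated genes ISG20 (-3.93 ± 0.56) and IRF7 (-3.37 ± 0.64), CCNG2 (-5.25 ± 0.82), SAMD9L (-4.79 ± 0.85), TNFSF13B (-4.69 ± 0.74), TMEM140 (-5.27) and IER5L (-5.49 ± 1.06). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these ran from 0.027 (IL1R1, ISG20) to 0.048 (BCL2, IER5L). IL2 stood at 3150 ± 3350 against 10.3 ± 13.3 CPM (8.27 ± 1.77), FOSL1 at 1.61 and FOS at -2.69, with adjusted p = 0.055, 0.16 and 0.19 in the same edgeR test with Benjamini-Hochberg adjustment.

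The list counts at 24 h that follow are from the fit without the replicate block. None of 24 DNA replication genes passed over all genes, and 20 were higher adjusted over the list alone. Mitosis genes had 2 of 22 higher, 17 adjusted over the list alone, and cytokines none of 16, 9 adjusted over the list alone. Lower were 2 of 19 interferon-stimulated genes (10 adjusted over the list alone), 1 of 13 anergy-associated genes (9) and none of 22 naive genes (6). Ribosome biogenesis genes had a median of 0.94, with 2 higher adjusted over the list alone. Camera gave an adjusted p of 6.8e-16 for mitosis, 3.3e-14 for DNA replication, 1.3e-07 for cytokines and 1e-08 for interferon-stimulated genes, and adjusted p = 0.22 with an estimated correlation for all 4. For ribosome biogenesis, anergy-associated and naive genes camera gave 1e-08, 0.00062 and 4.4e-06, and adjusted p = 0.35, 0.32 and 0.37 with an estimated correlation. Helper lineage factors and the p53 list were lower at a camera adjusted p of 0.034 and 0.043, or 0.068 and 0.1 with the replicate block, and adjusted p = 0.22 and 0.37 with an estimated correlation. AP-1 family genes did not pass (0.91).

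The replicate block raised the count at 24 h from 64 to 1300 genes, 446 higher and 854 lower, and all 64 were among them with the same direction. Under the block IL2 stood at 8.44 ± 1.28, G0S2 at 5.15 ± 0.44, IL3 at 4.79 ± 0.75, IER3 at 3.38 ± 0.59, RRM2 at 4.0 ± 0.68 and the transferrin receptor gene TFRC at 1.76 ± 0.41. MYB stood at -3.97 ± 0.35, the phosphatase gene PTPRJ at -3.07 ± 0.31, the co-stimulatory receptor gene CD27 at -1.85 ± 0.26 and FOSB at -3.05 ± 0.74. EdgeR's quasi-likelihood test with the replicate block and Benjamini-Hochberg adjustment gave 0.001 for G0S2 and MYB, 0.0055 for IL2 and 0.028 for FOSB. Without the block, leaving out either library with both antibodies left 0 of the 64 calls, with 2833 genes at an unadjusted p under 0.05 over all libraries and 1183 called by DESeq2. The count was 1 without replicate 1 of the CD3 group and 1543 without its replicate 2.

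At 60 h 8 genes differed with co-stimulation, 4 each way. PALLD, an actin-organising protein gene, stood at 5.91 ± 0.86, IL1R1 at 5.00 ± 0.69, the DNA sensor gene AIM2 at 4.14 ± 0.63 and JMY at 2.5 ± 0.33. CHST2 stood at 11.8 against 87.7 CPM (-2.89 ± 0.32) and APOBR at -3.75 ± 0.53. RAMP1 stood at -6.39 and was named after its values were seen. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment the values were 0.0068 for CHST2, 0.021 for JMY, 0.029 for IL1R1 and APOBR, 0.035 for PALLD and 0.047 for AIM2. IL2 stood at 5.57 ± 1.59, FOSL2 at 2.26 and BATF at 0.98, with adjusted p = 0.16, 0.19 and 0.19 in that edgeR test with Benjamini-Hochberg adjustment. Interferon-stimulated genes had a median of 1.18 with 1 of 19 higher adjusted over the list alone, mitosis genes 0.76 with none and amino acid genes 0.88. Their camera adjusted p was 9e-05, 9e-05 and 0.00016, and adjusted p = 0.56 with an estimated correlation for each. Cytokine and p53 genes passed camera at 0.036 and 0.048, and did not with the replicate block at 0.076 and 0.064. They had adjusted p = 0.57 and 0.56 with an estimated correlation.

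The replicate block in the fit of 14 libraries gave 385 genes at 60 h, 156 higher and 229 lower, including all 8, and 45 in a fit of only the 4 libraries compared. The replicate differences of the 2 groups at 60 h correlated at only 0.044, so the pairing that the block assumes has little support there. G0S2 stood at 4.71 ± 0.39 and CD27 at -3.34 ± 0.27 under the block. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave CD27 0.00048 with the block, 0.02 with the block and 4 libraries, and 0.056 without it. For G0S2 the same edgeR test with Benjamini-Hochberg adjustment gave 0.00077, 0.01 and 0.11. Without the block the count was 0 without replicate 1 of the group with both antibodies, 1 without replicate 1 of the CD3 group and 201 without its replicate 2.

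Whether the effect of co-stimulation differed between times was tested as an interaction. Between 24 h and 5 h edgeR called 0 genes, with 772 at an unadjusted p under 0.05 and 22 called by DESeq2. Between 60 h and 24 h edgeR called 0, with 758 at an unadjusted p under 0.05 and 70 called by DESeq2. JMY passed in the later interval with the replicate block (3.13 ± 0.38, adjusted p = 0.033 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), named after its value was seen. The group with both antibodies at 60 h enters this interval, and the pairing that the block assumes has little support for it. Without replicate 2 of the CD3 group at 24 h 1 gene passed in the earlier interval.

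In the electroporation experiment, the comparison of GFP control cells activated for 5 h with unactivated electroporated cells asks how pulsed cells responded to activation. The unactivated cells were pulsed without protein, so activation and the delivery of a protein cannot be told apart. NR4A2, an immediate early nuclear receptor gene, rose by 6.49 ± 0.34, CD69, an early activation marker, by 6.22 ± 0.38, IL2RA by 6.64 ± 0.41 and FOSL1 by 7.83 ± 0.64. XIRP1 was at least 303-fold higher and SPRY4, a feedback inhibitor gene of receptor signalling, at least 198-fold. LIF stood at a ratio of 849 to unactivated cells (counting interval 152 to 33600). RASGRP2 fell by 4.63 ± 0.40, and TMEM204 by 6.38 ± 1.08. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 5.9e-05 for NR4A2 and CD69 and 0.00014 for FOSL1.

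Of 10 AP-1 family genes 8 rose in GFP cells, 10 adjusted over the list alone. ATF3 rose by 6.65 ± 0.87, FOS by 4.55 ± 0.66, FOSL2 by 4.56, FOSB by 3.37, BATF by 2.53 and JUN by 1.28. JUNB stood at 1.18 and JUND at 1.56. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment their adjusted p was 0.1 and 0.083, and 0.0075 and 0.045 with the replicate block. IL2 rose by 8.18 ± 1.93 and IFNG by 6.73 ± 1.35, at adjusted p = 0.013 and 0.0048 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.096 and 0.06 with the replicate block. BATF at 0.016 and JUN at 0.042 in that edgeR test with Benjamini-Hochberg adjustment passed in no fit that left out an unactivated library or GFP replicate 2, where BATF had 0.07, 0.094 and 0.16 and JUN 0.2, 0.078 and 0.22. The adjusted p of IL2 was between 0.16 and 0.28 without any of the 4 libraries, and that of IFNG 0.07 without unactivated replicate 2 and 0.054 without GFP replicate 1, by the same edgeR test with Benjamini-Hochberg adjustment.

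Immediate early genes had 16 of 19 raised in GFP cells, with EGR3 at 6.78 ± 0.43, NF-kB targets 13 of 15, with REL at 4.90 ± 0.44, and surface molecules 14 of 20. Cytokines had 10 of 15 raised, with TNFSF14 at 7.47 ± 0.92, and chemokines 5 of 7, with IL8 at 7.60 ± 0.51. Ribosome biogenesis genes had 20 of 21 raised, amino acid genes 11 of 14 with PSAT1, a serine synthesis enzyme gene, at 4.51 ± 0.29, glycolysis genes 11 of 17 with 2 lowered and PKM at 3.96 ± 0.36, and heat shock genes 11 of 16 with HSPA5 at 2.74 ± 0.28. Cholesterol genes had 8 of 17 raised and 1 lowered, helper lineage factors 5 of 16 raised and 1 lowered with IRF4 at 5.56 ± 0.67, and anergy-associated genes 5 of 13 raised and 3 lowered with EGR2 at 7.95 ± 0.58. Naive genes had 10 of 22 lowered and 5 raised, with PIK3IP1 at -4.02 and BACH2 raised by 2.45. BCL2 family genes had 4 of 14 raised and 4 lowered, with PMAIP1 at 5.26 ± 0.32, the p53 list 6 and 6 of 16, with GADD45A at 5.86 ± 0.44, and interferon-stimulated genes 2 and 4 of 18, with MX2 at -2.53. Housekeeping genes had 6 of 12 raised, DNA replication genes 1 of 18 raised and 1 lowered, and mitosis genes 1 of 13 lowered. Memory and regulatory T cell markers had 3 of 12 raised and 2 lowered, 1 of 9 NK and cytotoxic genes was lowered, and no B cell, myeloid or CD8 marker passed.

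In total 4797 of 12583 genes differed between GFP and unactivated electroporated cells, 2624 raised and 2173 lowered. With total counts as the only scaling, which moved the median by -0.49, 1623 were raised and 3181 lowered. The count was 3029 and 2417 without unactivated replicates 1 and 2. Camera called 14 lists, from an adjusted p of 5.1e-21 for immediate early genes to 0.049 for housekeeping genes, and with an estimated correlation the adjusted p of these ran from 0.22 to 0.5. Helper lineage factors passed camera with the replicate block only (0.017 against 0.094), with adjusted p = 0.26 with an estimated correlation. Genes under 600 bases that code for no ribosomal protein had a median of 1.78 in this comparison, and longer genes had medians from -0.18 to -0.05. Whether recovery by transcript length entered the calls was not tested.

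The comparison of A-FOS with GFP cells, both activated for 5 h, asks which transcripts depend on AP-1 activity. Without the block no single gene passed. GBP5, a guanylate-binding protein gene induced by interferon gamma, stood at 42.7 and 90.3 CPM with A-FOS against 861 and 1110 CPM with GFP (-3.88 ± 0.50), GBP4 at 21 and 40 against 283 and 381 CPM (-3.44 ± 0.41) and GBP1 at 86.4 and 91.5 against 493 and 571 CPM (-2.58 ± 0.33). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.074 for GBP1, GBP4 and GBP5. With the replicate block in the same test it was 4.9e-07 for GBP1, 7.4e-08 for GBP4 and 0.0044 for GBP5. DESeq2 without the block gave adjusted p values of 4.1e-09, 6.7e-12 and 6.7e-12 in that order.

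The AP-1 genes themselves differed between A-FOS and GFP cells by less than the test could separate, at 0.32 ± 0.55 for FOS, 0.15 for FOSB, -0.42 for FOSL1, -0.28 for FOSL2, 0.10 for JUN, -0.35 for JUNB, -0.75 for BATF and -1.38 ± 0.64 for JUND. IL2 stood at 4.94 and 199 against 86 and 887 CPM (-2.25 ± 1.43), and IFNG at 5.53 ± 6.99 against 56.8 ± 42.9 CPM (-3.31 ± 1.08). All 10 had an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with and without the block. IL2 and IFNG had 2.2e-07 and 2.9e-07 in that edgeR test with Benjamini-Hochberg adjustment when no filter on low counts was used. With no filter calls also rose elsewhere, as from 64 to 1656 genes for co-stimulation at 24 h. The counts of both genes were the same, so these small values depend on the filter and not on closer replicates.

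With the replicate block 42 genes differed, 4 higher and 38 lower with A-FOS. TBX21, the Th1 regulator gene, stood at 9.99 and 70.5 against 91.9 and 542 CPM (-3.04 ± 0.32), the peptide transporter gene TAP1 at 49.8 and 71.1 against 237 and 836 CPM (-2.97 ± 0.33), and XIRP1 at 0 and 0.338 against 4.54 and 46.4 CPM (-7.17 ± 0.86). IFIT3 stood at -3.54 ± 0.63, the chemokine gene CCL4 at -3.41 ± 0.68 and CD274, which codes for PD-L1, at -1.78 ± 0.38. Higher genes were HMOX1, the heme oxygenase gene, at 716 and 952 against 157 and 390 CPM (1.79 ± 0.31), and the heat shock genes HSPA1A (1.93 ± 0.40) and HSPA1B (2.00 ± 0.38), near-identical copies whose separate values are uncertain. CCL4 also has close copies. RPL41, a ribosomal protein gene, stood at -3.62 ± 0.57. In edgeR's quasi-likelihood test with the replicate block and Benjamini-Hochberg adjustment, the adjusted p was 3.8e-08 for TBX21, 9.6e-07 for TAP1, 8.7e-07 for XIRP1, 0.0015 for HMOX1, 0.0016 for IFIT3, 0.0087 for CCL4, 0.012 for HSPA1A, 0.0032 for HSPA1B, 0.00046 for RPL41 and 0.013 for CD274. Without the block the adjusted p was 1 for TBX21, 0.34 for TAP1 and 0.64 for XIRP1 in edgeR's test with Benjamini-Hochberg adjustment. The electroporated fit had 3 residual degrees of freedom without the block and fewer with it. P-values with the block, here and for the GBP genes above, therefore lean on spread shared across genes. For GFP against unactivated cells the lowest adjusted p in that edgeR test with Benjamini-Hochberg adjustment went from 5.9e-05 to 1.6e-18 with the block. The size of such small values is thus uncertain.

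Among the lists, none of 18 interferon-stimulated genes passed over all genes and 2 were lower adjusted over the list alone, with a median of -1.07. Between same-numbered libraries, with 0.5 CPM added, their median was -0.76 and -0.64. With the trend of fold change with transcript length taken out, the 95% interval of their median ran from -2.09 to 0.04. That interval takes genes as independent and does not measure the spread between libraries. Chemokines had a median of -2.52 over 7 genes, surface molecules -0.51 over 20 with 1 lower adjusted over the list alone, and NK and cytotoxic genes -1.45 over 9. Camera gave these an adjusted p of 4.6e-11, 4.9e-08, 3.4e-05 and 0.004, and adjusted p = 0.12, 0.15, 0.63 and 0.78 with an estimated correlation. It placed the 15 cytokine genes lower at 2.5e-06, with adjusted p = 0.78 with an estimated correlation. Helper lineage factors (-0.57) and NF-kB targets (-0.24) were lower and heat shock genes (0.08) higher by camera at 0.009, 0.036 and 0.036, and had adjusted p = 0.78, 0.9 and 0.86 with an estimated correlation. Immediate early genes had a median of -0.34 and passed with the replicate block only (camera adjusted p = 0.042 against 0.078, and adjusted p = 0.92 with an estimated correlation), and AP-1 family genes had a median of -0.33 at 0.33.

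EdgeR's quasi-likelihood test called 0 of 12583 genes without the block, with 267 at an unadjusted p under 0.05. That is below the share of 0.05 that arises with no effect. DESeq2, which made more wrong calls than edgeR in simulation, called 25, of which 24 were lower. The count was 9 without GFP replicate 1 and 6 without GFP replicate 2. A-FOS replicate 2 held 350 genes at 2 to 5 counts, against 756 to 1359 in the other libraries of the series, and 12668 genes with a count from 20140677 reads. Whether a filter on low counts was applied to it is not given, so zeros and low counts in it, and bounds that rest on them such as that of MMP28 below, are uncertain.

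**Figure D3:**
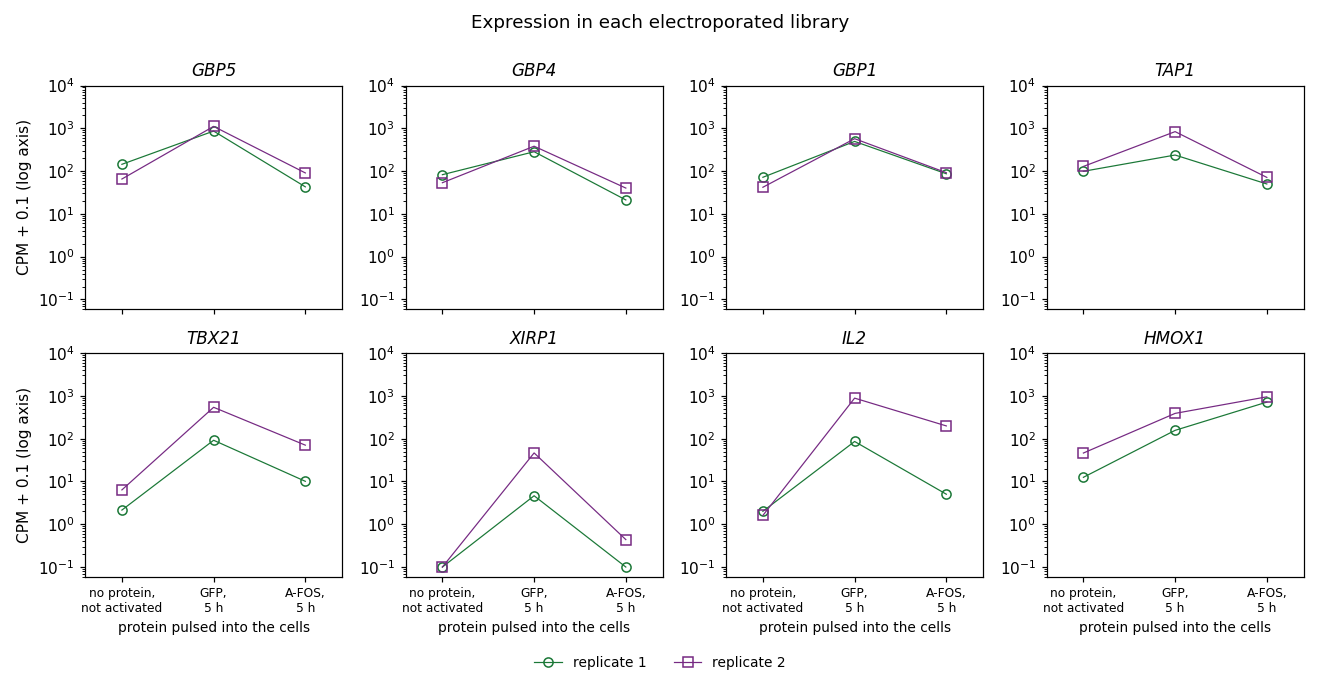
Expression of 8 genes in the 6 electroporated libraries, in CPM plus 0.1 on a log axis, by the protein pulsed into the cells, with lines joining libraries of the same replicate number. GBP5, GBP4, GBP1, TAP1, TBX21 and XIRP1 are lower with A-FOS than with GFP in both replicate numbers, and HMOX1 is higher.

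Against unactivated electroporated cells, A-FOS cells still differed in 4270 genes, 2328 raised and 1942 lowered. Here too, activation and the delivery of a protein cannot be told apart. SPRY4 was at least 171-fold higher, LIF stood at a ratio of 385 (68.6 to 15200), FOS rose by 4.87 ± 0.67 and FOSL1 by 7.41 ± 0.63, and MMP28 was at least 100-fold lower. IL2 rose by 5.93 ± 1.78, at an adjusted p of 0.036 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.2 with the replicate block, 0.38 and 0.26 without unactivated replicates 1 and 2, and 0.45 without A-FOS replicate 2. Immediate early genes had 16 of 19 raised, AP-1 family genes 7 of 10, cytokines 9 of 15 and chemokines 1 of 7. None of 18 interferon-stimulated genes was raised and 6 were lowered (camera adjusted p = 0.0064, and adjusted p = 0.24 with an estimated correlation). With total counts as the only scaling, which moved the median by -0.4, 1511 genes were raised and 2778 lowered. The count was 2499 and 1980 without unactivated replicates 1 and 2 and 1960 without A-FOS replicate 2.

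Whether genes raised by co-stimulation are the ones lower with A-FOS was asked from libraries that share no control. With no call in either comparison at 5 h the overlap of calls was 0. It was 0 with the replicate block too, where 38 genes were lower with A-FOS and none higher with co-stimulation. With the block in fits of the 4 libraries compared, chosen after the data were seen, 17 of 498 genes higher with co-stimulation were among 72 lower with A-FOS, against 3.44 for independent lists (one-sided Fisher p = 3.2e-08, which takes genes as independent). Across 12066 genes, which are not independent replicates, the fold changes had r = -0.11 and rho = -0.2. The correlation rests on single libraries. It was 0.118 without A-FOS replicate 1 and 0.026 without GFP replicate 2, and -0.214 and -0.237 without A-FOS replicate 2 and GFP replicate 1. Of the 200 genes with the smallest p among those higher with co-stimulation under the block, a set chosen after the data were seen, 184 were tested with A-FOS. Their median was -0.35, and 145 of the 184 (78.8%) were lower, against 52.9% of all genes. Camera gave 1.3e-07 for this set, with p = 0.34 with an estimated correlation and 0.47 by fry.

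For genes raised by CD3 and CD28 at 5 h in untouched cells, the overlap with genes lower with A-FOS was 0 without the block, where A-FOS had no call. It was 25 genes with the replicate block in both, against 10.5 for independent lists (one-sided Fisher's exact test, p = 9.9e-07), from 3327 raised and 38 lowered among 12066 genes. Fisher's test takes genes as independent. A gene is also more readily called lower with A-FOS if activated cells express it well, which favours genes raised by activation. Independent lists may thus understate the overlap that arises without AP-1, here and for co-stimulation above, and the excess does not show selectivity. DESeq2 gave 16 against 4.89 (one-sided Fisher's exact test, p = 1.2e-06). Without GFP replicate 1 and without the block it was 9 against 2.11.

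Whether the 5 h response differed between electroporated GFP cells and untouched cells was tested as an interaction over all 20 libraries. The unactivated electroporated cells had received no protein, so the interaction also holds any effect of the GFP pulse. Of 13416 genes 2 passed. RIT1, a RAS-related GTPase gene, stood at 31 and 44.1 CPM in naive and 20.2 and 32.2 CPM in activated untouched cells, and at 39.7 and 37.5 CPM in unactivated and 325 and 207 CPM in GFP cells (3.30 ± 0.48). TCF19, a growth-regulated gene, stood at 14.4 and 19.3 CPM in naive and 0 in both activated untouched libraries, and at 10.7 and 10.5 against 2.07 and 0.893 CPM after electroporation. Both had an adjusted p of 0.031 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the replicate block 7 genes passed, these and ACY1, C7orf50, HMOX1, ILDR2 and P2RY10, and DESeq2 called 94. The count was 115 without GFP replicate 2. It was 1 without unactivated electroporated replicate 1 or replicate 1 of the activated untouched cells, and 0 without naive replicate 2, activated untouched replicate 2, unactivated electroporated replicate 2 or GFP replicate 1.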

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

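The tests of explanations in this part were chosen after the result was seen, except the test without the 100 most abundant genes. With groups of 2, no count of other splits of the samples was made. The interaction between electroporation and activation at 5 h passed for RIT1, at a difference of 3.30, and for TCF19, at a difference of 7.67, whose fitted size depends on 0 counts in activated untouched cells.

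Guanylate-binding protein genes, a family picked because of these values, stood lower with A-FOS than with GFP. The 6 tested members stood at -1.27 ± 0.30 for GBP2, -1.41 ± 0.54 for GBP3, -2.58 ± 0.33 for GBP1, -3.44 ± 0.41 for GBP4, -3.88 ± 0.50 for GBP5 and -5.21 ± 1.63 for GBP7. The last is a fitted value, and the same-numbered GBP7 libraries differed by -2.43 and -3.17 with 0.5 CPM added. None of the 6 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without the block, and GBP3 (0.16) and GBP7 (0.31) did not with it. Poorer recovery of short transcripts in the A-FOS libraries does not account for this, since the highest of the 6 stood at -1.25 after the trend of fold change with transcript length was taken out. The few low counts of A-FOS replicate 2 do not either, since the highest stood at -1.15 between the replicates numbered 1 alone. A lower interferon response under A-FOS stays open as a hypothesis, and other differences between the pulses were not tested.

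Ribosomal protein genes were also lower with A-FOS, with a median of -0.42 over 81 genes (quartiles -0.71 and -0.21), and made up 8 of the 38 genes lowered under the block. Recovery of short transcripts is a candidate explanation, as genes under 600 bases that code for no ribosomal protein had a median of -0.36 (95% interval -0.53 to -0.26, 226 genes), and the ribosomal median was -0.16 once the length trend was taken out. The interval takes genes as independent and does not measure the spread between libraries. A difference by length was not particular to A-FOS. In GFP against unactivated cells such short genes had a median of 1.78, and longer genes had medians from -0.18 to -0.05. For RPL17, at 532 and 282 CPM with GFP and 67.5 and 38.4 CPM with A-FOS, allotment of reads to an overlapping read-through entry may contribute, since the summed reads changed by only -0.59. A response of these genes to A-FOS was not tested and stays open.

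Fewer genes were detected 5 h after activation at a common depth. Naive libraries had 12593 and 12578 genes, libraries with both antibodies 11581 and 11703, and those with CD3 antibody alone 11914 and 11867, a mean difference of -819. Without the 100 most abundant genes of each library, and at a lower common depth, fewer genes were still detected at 5 h, with a mean difference of -844. These very abundant genes therefore do not account for all of the fall. How much they contribute cannot be read from the size of the differences, because the depths were not the same. Too few distinct molecules stay open as an explanation, because read counts do not measure molecules. Each of the 4 libraries had at least 1228 genes at 2 to 5 counts, and genes at 1 count numbered 489 and 840 with both antibodies and 716 and 823 with CD3 antibody alone, against 670 and 700 in naive cells. A narrower set of transcripts after activation stays open too, and the top 1000 genes held 62.5% of counts at 5 h against 55.7% in naive cells.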

How the results depend on the processing

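Alternatives named as added after the data were seen are the block in a fit of 4 libraries, the block without the group with both antibodies at 60 h, overlapping genes left out, the length minimum, the separate naive libraries and the set of 200 genes. The counts against naive or unactivated cells stayed within 1.5 times under every planned setting but the block and leaving out a library, and no named gene that passed changed sign under any setting. Some that did not pass did, such as JUN at 5 h against naive cells (0.52, and -1.55 without replicate 1 of the 5 h group). Where a value moved, the cause was not tested.

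Of the co-stimulation counts, 0 genes at 5 h became 134 with no filter, 28 with DESeq2, 1052 with the replicate block in a fit of 4 libraries and 22 with the block without the 60 h group. The 64 genes at 24 h became 97 with total counts only, 1656 with no filter, 1300 with the replicate block, 1183 with DESeq2, 246 with all 20 libraries, 0 with only 4 libraries (edgeR, against 2833 at an unadjusted p under 0.05 in the fit of 14), 3532 with the block and 4 libraries, 2576 with the block without the 60 h group and 104 with overlapping genes left out. The 8 genes at 60 h became 910 with no filter, 385 with the replicate block, 451 with DESeq2, 21 with all 20 libraries, 22 with only 4, 45 with the block and 4 libraries and 13 with overlapping genes left out. The 0 genes of A-FOS against GFP became 54 with no filter, 42 with the replicate block, 25 with DESeq2, 6 with all 20 libraries, 80 with the block and 4 libraries and 34 with the block over transcripts of at least 1000 bases.

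For CD3 antibody alone against naive cells the replicate block gave 3843 genes at 24 h and 3704 at 60 h, and 4574 and 4446 without the 60 h group with both antibodies. The interactions gave 212, 213 and 301 genes with no filter and 22, 70 and 94 with DESeq2. They gave 0, 1 and 7 with the replicate block, and the interaction with electroporation gave 0 with total counts only. The overlap of genes higher with co-stimulation and lower with A-FOS was 17 with the block and 4 libraries, against 3.44 for independent lists. That of genes raised by both antibodies at 5 h and lower with A-FOS was 16 with DESeq2, 25 with the replicate block and 58 with the block and 4 libraries (22.1 for independent lists). The correlation of co-stimulation and A-FOS was -0.278 over genes of at least 10 CPM. The set of 200 genes had p = 0.34 by camera with an estimated correlation and 0.47 by fry. Genes lowered with and without CD28 antibody at 24 h numbered 1533 with the replicate block, and at 60 h 1342 with it and 970 with no filter. With naive replicate 1 for both antibodies and replicate 2 for CD3 antibody alone, 1556 genes were raised and 1775 lowered in both at 5 h, 782 and 389 at 24 h, and 656 and 214 at 60 h. The other way round the numbers were 1570 and 1835, 410 and 192, and 527 and 146.

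Leaving out 1 library at a time, the counts against naive cells ran from 4937 to 5289 at 5 h, 3131 to 4534 at 24 h and 2942 to 3734 at 60 h with both antibodies, and from 3585 to 4325, 655 to 2757 and 739 to 2560 with CD3 antibody alone. Co-stimulation ran from 0 to 1 at 5 h, 0 to 1543 at 24 h and 0 to 201 at 60 h. A-FOS against GFP ran from 0 to 9, GFP against unactivated cells from 2417 to 4686 and A-FOS against unactivated cells from 1960 to 3809. The interactions ran from 0 to 1 between 24 h and 5 h, 0 to 0 between 60 h and 24 h, and 0 to 115 with electroporation. The overlaps with A-FOS ran from 0 to 0 for co-stimulation and 0 to 9 for both antibodies. The correlation ran from -0.237 to 0.118 and changed sign without A-FOS replicate 1 (0.118) and without GFP replicate 2 (0.026).

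Among values of single genes in a comparison, the replicate block left 552 on the same side of the threshold, brought 114 past it and took 3 back. DESeq2 left 564, brought 99 past and took 5 back, and total counts only left 655. With 1 library left out at a time, 2356 values stayed, 68 passed and 252 no longer did. For lists, camera with an estimated correlation lost 88 calls and the replicate block gained 6 and lost 4. The set test on called genes was not run, as co-stimulation at 5 h had no call. Depth limits genes near the floor most, since naive replicate 2 held 2020137 reads.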

Other observations

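The 15 families examined outside the fixed lists were chosen after the data were seen, and directions are relative to a median shift of -0.48 at 5 h under total-count scaling, which turns none of those given. Of 38 proteasome subunit genes, 33 rose at 5 h of activation through CD3 and CD28, 35 at 24 h and 35 at 60 h, and none fell, with medians of 1.74, 2.09 and 1.54. Of 9 genes of the chaperonin that folds actin and tubulin, 8 rose at each time. Aminoacyl-tRNA synthetase genes, which charge transfer RNAs, had 17 of 18 raised and 1 lowered at 5 h, 11 raised at 24 h and 14 at 60 h. The GIMAP genes, GTPases of resting lymphocytes, had all 6 lowered at 5 h and 24 h and 5 lowered at 60 h, with medians of -4.48, -3.75 and -3.18. The camera adjusted p of these families ran from 9.4e-15 to 2e-04, and adjusted p ran from 0.21 to 0.35 with an estimated correlation. Of the families not described here, initiation factors (34 of 57 raised), respiratory chain subunits (29 of 82), nuclear pore proteins (12 of 20) and guanylate-binding proteins (4 of 7) also passed camera at 5 h, and none with an estimated correlation. Ribosomal proteins, core histones, snoRNA host genes, solute carriers and tubulins did not pass at 5 h.

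In GFP cells against unactivated electroporated cells, the same families had 32 of 38 proteasome genes raised and 1 lowered, 8 of 9 chaperonin genes raised, 16 of 18 synthetase genes raised and 1 lowered, and all 6 GIMAP genes lowered. Zinc finger genes named ZNF had 24 of 437 raised and 164 lowered at 24 h, and 15 raised and 161 lowered at 60 h. Their camera adjusted p was 6.4e-06 and 1.9e-08, and adjusted p = 0.23 and 0.27 with an estimated correlation. Kinesins, motor proteins of the spindle and of transport, had 13 of 29 lowered and 4 raised at 5 h and 16 raised and 1 lowered at 60 h, where the camera adjusted p was 5.9e-09, and adjusted p = 0.08 with an estimated correlation.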
